A study of Homo sapiens with 4 samples.

How the data were processed

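The series holds 4 RNA-seq libraries of HCT116 cells, 2 from cells with a control hairpin, shNC2 in the sample titles and shNC in the series text and here, and 2 from cells with a WDR43 hairpin. Per the labels' protocols, RNA was extracted with Trizol after lentiviral infection for 48 h and puromycin selection for 3 days, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic, FastQC, HISAT2, RSEM and edgeR were used, with the GRCh38 genome, and the notes as used here give no role or order for these tools. The annotation release and the strand setting are not given in the sources used here. The deposited values were read as FPKM, a measure of fragments scaled by transcript length and by the mapped total. This unit was inferred from the values, which sum to 393582 to 413758 per library, and TPM over part of the genes is not excluded.

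Each library listed 29286 genes by Ensembl identifier, besides 1 blank entry that was left out. Of these, 29170 had a symbol in the name table and 28468 a position in GENCODE release 29, from which coordinates were taken, and 2348 were at 0 in all libraries. Low values were checked for whole-read steps between each pair of libraries. The fullest 1% window of ratios held at most 1.67% of genes, so reads were not recovered and the depth stays unknown. No interval that needs a read count is given. The values used here held none for WDR43 and for 15 genes of the fixed lists, so these were not analysed here.

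Before the data were examined, the groups, the main design, the rule for named genes, the gene lists and most alternatives were fixed. The main design for FPKM values used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genes at 1 FPKM or more in at least 2 libraries, the group as the only term, and empirical Bayes moderation with a mean-variance trend and robust settings. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 13303 genes, with a threshold of 0.05 and 2 residual degrees of freedom per gene before moderation. Fold changes in log2 are on the log2(FPKM + 1) scale, which understates the change of low genes. Ratios of mean FPKM are given where a fold is stated for a single gene. Counts of genes changed at least 2-fold, and the test against a 1.5-fold change, use the log2(FPKM + 1) scale. No scaling was added to the deposited values.

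The genes named are MYC, MDM2, MDM4, CDKN1A, RPL5 and RPL11 whatever their result, the 8 largest rises and 8 largest falls among changed genes with a symbol, a mean of at least 5 FPKM and groups that do not overlap, and, in each list, up to 4 changed members with the smallest p-values, or the 2 smallest where none changed. Some genes that this rule selects are not reported here. There were 29 lists with 890 distinct genes, of which 735 were tested. The 26 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation called 0 of the 26, with 1 at an unadjusted p below 0.05, and fry, which tests whether a list's genes move one way on balance, called 6. The estimated correlation rests on 2 residual degrees of freedom.

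The alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, robust settings off, a replicate block and leaving out each library in turn. A filter at 5 FPKM, upper-quartile scaling, a test against a 1.5-fold change, a crossed block and protein-coding genes alone were added after the data were seen. A fit without a library assumes that the lone library of a group varies like the other group.

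The model was tested on simulated data for 13303 genes in 20 simulations with 200 changed genes each. With gene variances drawn from the fitted prior, it recovered 1.87% of genes changed 1.25-fold, 36.6% of those changed 1.5-fold and 93.8% of those changed 2-fold, and 5.09% of calls were false. With each gene's shrunken variance taken as true, the shares were 21.9%, 92.5% and 99.8%, and 11.3% of calls were false, above the nominal 5%. The first simulation was added after the second had given more false calls than intended. A list shifted by 0.3 on the log2 scale was called in 20 of 20 simulations in both. Simulated genes varied independently, so this does not test list calls among correlated genes. The 200 changed genes were not drawn from genes at low levels, so recovery there is unknown. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.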

Results

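RNA sequencing was carried out on HCT116, an established human colorectal carcinoma cell line. Cells had been infected with lentiviruses for a short hairpin against WDR43 (shWDR43) or for a control hairpin (shNC2 in the sample titles, shNC here), kept for 48 h, and then selected with puromycin for 3 days. Each group had 2 libraries, 4 in all, and the comparison asks how the transcriptome differed after knockdown of WDR43, a nucleolar protein of the small-subunit processome that assembles the small ribosomal subunit. The values covered 29286 genes and were read as FPKM, a unit inferred from the values. They summed to 393582 and 413758 in shNC replicates 1 and 2 and to 411816 and 402393 in shWDR43 replicates 1 and 2, and 13373, 13058, 13022 and 13045 genes reached 1 FPKM in that order. Read totals were not used here, so the depth behind each value is unknown. Libraries of the same group were closest to each other: the SD of their log2 difference across genes was 0.245 for shNC and 0.177 for shWDR43, against 0.281 to 0.317 between groups. The labels do not state whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

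Cells with the WDR43 hairpin had higher levels of many p53 target genes and lower levels of many amino-acid response genes. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.13-fold, from 74.7 ± 1.40 to 234 ± 6.60 FPKM (mean ± SD, n = 2 per group). ASNS, the asparagine synthetase gene, fell to 0.378 of its control level, from 112 ± 15.1 to 42.3 ± 1.05 FPKM. Of 38 tested p53 targets, 24 rose and 1 fell, and of 30 tested ATF4 and amino-acid response genes, 15 fell and 0 rose, with adjusted p = 0.268 and adjusted p = 0.328 with an estimated correlation. Without shWDR43 replicate 2, 16 of the p53 targets rose. In the WDR43 partner and small-subunit processome list 1 of 42 tested members changed. That count moved with the library left out, as did the count over all tested genes.

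WDR43 itself (ENSG00000163811) lies on chromosome 2 at 28894643 to 28948222, plus strand, in the GENCODE release 29 annotation of GRCh38. The values used here held none for WDR43, so its level was not analysed here and the knockdown labels could not be checked against their target. Of the other genes fixed for reporting, CDKN1A passed the test with a log2 change of 1.63 ± 0.09 (SE) and an adjusted p of 0.000865. MYC was at 124 ± 11.6 FPKM in shNC and at 130 ± 6.42 FPKM in shWDR43 (mean ± SD, n = 2 per group), a log2 difference of 0.07 ± 0.10 (adjusted p = 0.703). MDM2, a ubiquitin ligase gene, was at 17.9 and 15.4 FPKM against 19.0 and 21.003 FPKM, a log2 difference of 0.25 ± 0.10 that did not pass (adjusted p = 0.173). The MDM2 difference was 0.35 without shNC replicate 1 and 0.15 without shNC replicate 2. MDM4 was at 36.2 and 22.1 FPKM in shNC against 20.9 and 23.1 FPKM, a log2 difference of -0.35 (adjusted p = 0.296). The MDM4 difference was -0.70 without shNC replicate 2 and -0.00937 without shNC replicate 1. RPL5 and RPL11 encode ribosomal proteins known to bind MDM2. RPL5 had a mean of 755 ± 105 FPKM in shNC and 752 ± 10.2 FPKM in shWDR43. RPL11 was at 575 and 764 FPKM in shNC and at 568 and 514 FPKM in shWDR43, a log2 difference of -0.29 (adjusted p = 0.265). The RPL11 difference was -0.50 without shNC replicate 1 and -0.09 without shNC replicate 2. MDM2 overlaps CPM and RPL5 overlaps DIPK1A, each on the opposite strand. The strand setting of the counting is not given in the sources used here, so the levels of MDM2 and RPL5 are uncertain.

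Across 13303 tested genes, 833 changed at an adjusted p below 0.05 (limma on log2 of FPKM + 1), of which 637 were higher and 196 lower in shWDR43. Changes were mostly small, with a median absolute log2 change of 0.53. By at least 1 on the log2(FPKM + 1) scale 34 genes changed, 24 upward and 10 downward. Low genes can pass 2-fold in FPKM without being counted here, as ABCB1 did, at a log2 change of 0.80 and a ratio of 2.51. The split between higher and lower genes depended on scaling. It was 310 to 140 after median-ratio scaling and 302 to 292 after upper-quartile scaling, which lowered the median log2 change of all genes by 0.07, from 0.05 to -0.03. Without the filter on low values 17 genes changed, and 1762 changed without shNC replicate 1, 2586 without shNC replicate 2, 377 without shWDR43 replicate 1 and 447 without shWDR43 replicate 2. Against a 1.5-fold change, limma called 3 genes, CPA4 and CDKN1A among them, and an exact permutation test of a single gene with 2 libraries per group cannot go below p = 0.333.

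**Figure D1:**
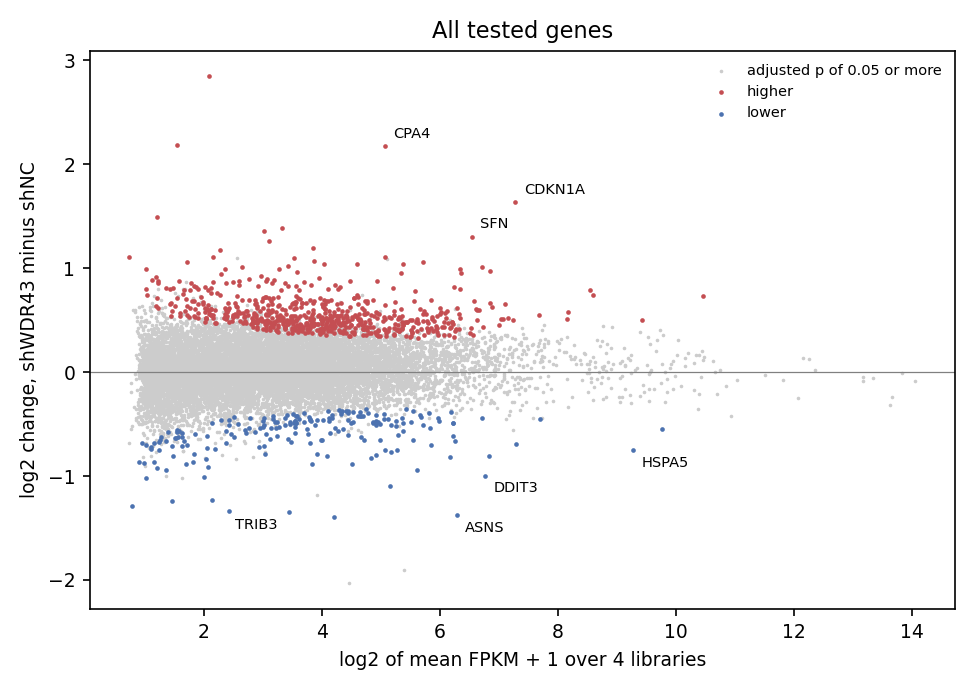
Log2 change (shWDR43 minus shNC, of FPKM + 1) against the log2 of mean FPKM + 1 over 4 libraries for each of 13303 tested genes. Red points are the 637 genes that were higher and blue points the 196 that were lower at an adjusted p below 0.05, grey points the rest.

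The largest rise among genes with a mean of at least 5 FPKM was that of CPA4, a carboxypeptidase gene on chromosome 7 (130293134 to 130324180). It went from 11.2 ± 1.36 to 54.0 ± 1.91 FPKM, a log2 change of 2.18 ± 0.10 (SE; adjusted p = 0.000539). CDKN1A (chromosome 6, 36676460 to 36687339) followed. SFN, the 14-3-3 sigma gene and a known p53 target (chromosome 1, 26863138 to 26864457), rose from 52.6 ± 4.53 to 131 ± 9.59 FPKM, a log2 change of 1.30 ± 0.10. BTG2, an antiproliferative gene (chromosome 1, 203305491 to 203309602), rose from 7.75 ± 0.494 to 19.0 ± 1.08 FPKM, and PLK3, a stress-responsive polo-like kinase gene (chromosome 1, 44800225 to 44805990), from 20.3 ± 0.336 to 44.8 ± 0.555 FPKM. BTBD19, whose start lies 3' of PLK3 on the same strand (44808482 to 44815585), rose from 3.54 ± 0.335 to 10.6 ± 0.00198 FPKM. The lysosomal protein gene CD68 (chromosome 17, 7579467 to 7582113) rose from 4.10 ± 0.739 to 11.2 ± 0.746 FPKM. KRTAP2-3 (chromosome 17, 41059240 to 41060114) had a log2 change of 1.38 ± 0.09, which is uncertain because near-identical keratin-associated protein genes can share its reads. PLK3 overlaps DYNLT4 on the opposite strand.

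The largest falls included several genes of the amino-acid response. ASNS (chromosome 7, 97852118 to 97872542) fell by 1.38 ± 0.11 on the log2 scale (SE, adjusted p = 0.00304), and a short gene that overlaps it, ENSG00000226744, fell by 1.40. Another gene, ENSG00000284707, with a mean of 1.21 FPKM, overlaps ASNS over its whole length on the same strand, so the level of ASNS is uncertain. TRIB3, a pseudokinase gene induced by ATF4 (chromosome 20, 362835 to 397559), went from 14.7 ± 2.18 to 5.13 ± 0.313 FPKM, a log2 change of -1.35 ± 0.12. DDIT3, the gene of the stress transcription factor CHOP (chromosome 12, 57516588 to 57521737), went from 145 ± 29.7 to 71.4 ± 2.40 FPKM, a log2 change of -0.997 ± 0.136. Its neighbour MBD6 (57520710 to 57530148) lies on the opposite strand and overlaps it, and its log2 change of -0.88 ± 0.10 is therefore uncertain, as is that of DDIT3. AARS1, the cytosolic alanyl-tRNA synthetase gene (chromosome 16, 70252295 to 70289543), fell from 63.0 ± 4.81 to 32.3 ± 0.255 FPKM. The long non-coding RNA gene OLMALINC (chromosome 10, 100373513 to 100454043) fell from 35.5 ± 2.63 to 19.6 ± 0.156 FPKM. ZC3H11A (chromosome 1, 203795654 to 203854999) went from 47.6 ± 3.58 to 22.0 ± 5.19 FPKM while ZBED6, which lies within it on the same strand, went from 7.97 ± 0.417 to 14.5 ± 0.593 FPKM. Reads of ZC3H11A and ZBED6 cannot be assigned to either with certainty.

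**Figure D2:**
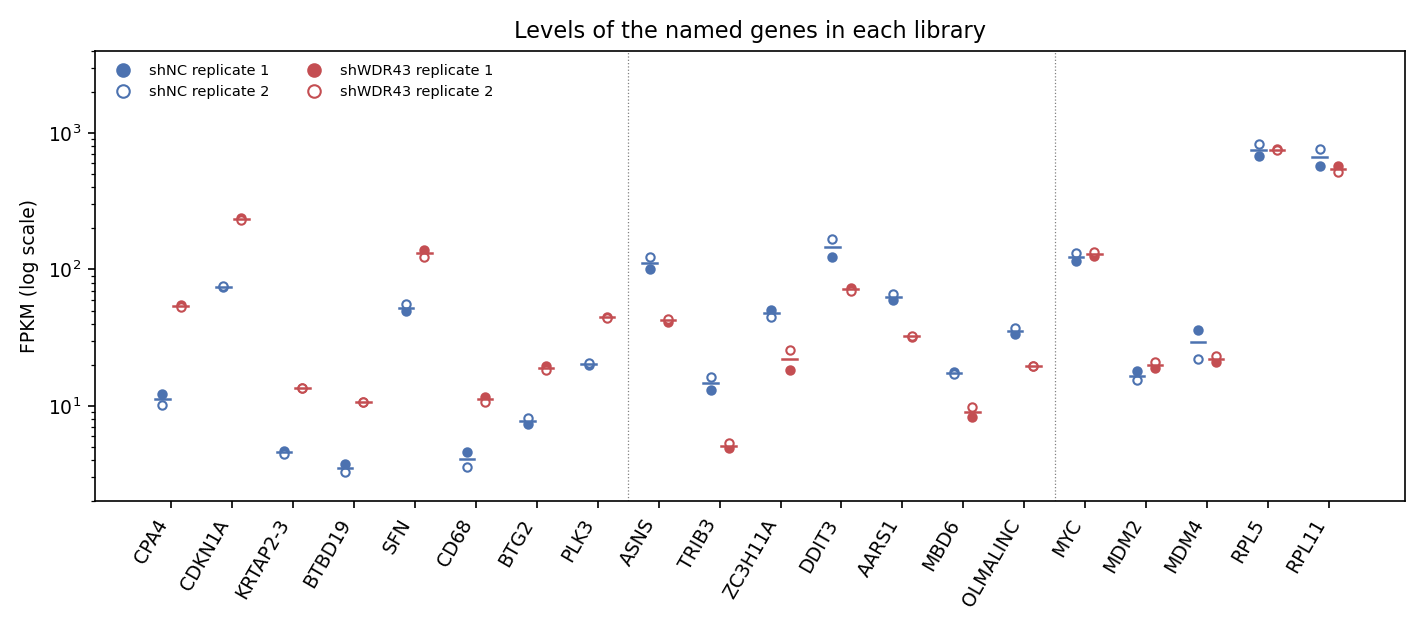
FPKM on a log scale of the reported genes named by fixed rule in each of 4 libraries, with filled circles for replicate 1, open circles for replicate 2 and a bar at each group's mean. The 8 largest rises stand at the left, 7 of the 8 largest falls in the middle and other genes fixed for reporting at the right, and CDKN1A, plotted once among the rises, was at 73.8 and 75.7 FPKM in shNC and at 239 and 229 FPKM in shWDR43.

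Among p53 target genes, 24 of 38 tested members rose and 1 fell, or 30 and 1 when adjusted over the list alone, with a median log2 change of 0.52. CDKN1A, PLK3 and BTG2 were joined by TP53INP1, a p53-induced nuclear protein gene, at 6.07 ± 0.741 and 13.3 ± 0.158 FPKM. The member that fell was SESN2, with a log2 change of -0.53, a stress gene that is also on the ATF4 list and was singled out after its value was seen. The list was called upward by camera (adjusted p = 1.83e-15), with adjusted p = 0.268 with an estimated correlation. Without shWDR43 replicate 2, 16 members rose. Apoptosis regulators had 5 of 26 members that rose and 0 that fell, or 6 and 0 when adjusted over the list alone. The pro-apoptotic BIK went from 4.37 ± 0.223 to 9.21 ± 0.155 FPKM and BAK1 from 3.16 ± 0.209 to 4.98 ± 0.363 FPKM, while BIRC3, which encodes an inhibitor of apoptosis, went from 3.77 ± 0.0670 to 6.72 ± 0.0553 FPKM. CYCS, the cytochrome c gene, also rose. Camera gave an adjusted p of 0.00283 for this list, and adjusted p = 0.322 with an estimated correlation. The number of apoptosis regulators that rose was 10 without shNC replicate 2, 2 without shWDR43 replicate 1, 3 without shWDR43 replicate 2 and 3 under either scaling.

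The ATF4 and amino-acid response list had 15 of 30 members that fell and 0 that rose, or 21 and 1 when adjusted over the list alone, with a median log2 change of -0.48. Besides ASNS, TRIB3 and AARS1, the cystine transporter gene SLC7A11 fell from 6.73 ± 0.810 to 2.07 ± 0.262 FPKM. Camera called the list downward (adjusted p = 5.78e-15), with adjusted p = 0.328 with an estimated correlation. Under median-ratio scaling 13 fell, and under upper-quartile scaling 17 fell. The list median in each pair of a shWDR43 and a shNC library ran from -0.56 to -0.39, and 5 members had a positive log2 difference. In the unfolded protein response list, 6 of 26 members fell and 0 rose, or 11 and 0 when adjusted over the list alone. HSPA5, the endoplasmic reticulum chaperone BiP, went from 777 ± 110 to 459 ± 4.96 FPKM, HERPUD1 from 144 ± 0.563 to 82.1 ± 5.22 FPKM, XBP1 from 37.9 ± 7.80 to 23.5 ± 1.07 FPKM and HSP90B1 from 1025 ± 94.4 to 702 ± 15.4 FPKM. The camera adjusted p was 2.58e-06, and adjusted p = 0.322 with an estimated correlation. In this list 12 fell without shNC replicate 1, 10 fell and 2 rose without shNC replicate 2, and 2 fell without shWDR43 replicate 1 or 2 and under median-ratio scaling. Cholesterol synthesis genes had 4 of 25 members that fell and 0 that rose, or 5 and 0 when adjusted over the list alone. These were INSIG1, which restrains sterol regulatory processing, at a log2 change of -0.65, the sterol carrier STARD4 at -0.62, the transcription factor SREBF2 at -0.47 and the enzyme MSMO1 at -0.38. Camera gave an adjusted p of 0.00152 for this list, and adjusted p = 0.322 with an estimated correlation. Without shNC replicate 1, 4 fell and 1 rose, without shNC replicate 2, 7 fell and 2 rose, and 2 fell without shWDR43 replicate 1 or 2.

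Genes of DNA replication and the G1/S transition had 11 of 40 members that rose and 0 that fell, or 25 and 0 when adjusted over the list alone, with a median log2 change of 0.33. CCNE1, the cyclin E1 gene, went from 5.49 ± 0.366 to 11.9 ± 0.0409 FPKM, the clamp gene PCNA from 61.1 ± 7.68 to 93.7 ± 1.02 FPKM, and the helicase subunit genes MCM4 and MCM6 had a log2 change of 0.55 each. Camera gave an adjusted p of 1.21e-09, and adjusted p = 0.322 with an estimated correlation. The number that rose was 17 without shNC replicate 1, 25 (with 1 that fell) without shNC replicate 2, 5 without shWDR43 replicate 1, 4 without shWDR43 replicate 2 and 7 under median-ratio scaling. Of 40 G2/M and mitosis genes, 2 fell and 1 rose, or 5 and 1 when adjusted over the list alone, and 31 had a negative log2 difference. The kinetochore genes CENPF and CENPE had log2 changes of -0.53 and -0.54, and CKS2, a cyclin-dependent kinase subunit gene, rose by 0.58. The list was called downward by camera (adjusted p = 1.34e-05), with adjusted p = 0.328 with an estimated correlation. In it 10 fell and 2 rose without shNC replicate 1, 7 fell and 3 rose without shNC replicate 2, 1 fell and 1 rose without shWDR43 replicate 1 and under median-ratio scaling, and 5 fell and 1 rose under upper-quartile scaling. None of 40 DNA repair genes passed the test with limma, over all genes or over the list alone. XRCC5 had a log2 difference of 0.26 (adjusted p = 0.133, unadjusted p = 0.0261). Of the repair genes, 2 rose and 1 fell without shNC replicate 1, 5 rose and 1 fell without shNC replicate 2 and 1 fell without shWDR43 replicate 2.

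Nuclear genes of the mitochondrial respiratory chain had 11 of 39 members that rose and 0 that fell, or 28 and 0 when adjusted over the list alone, with a median log2 change of 0.36. COX7C went from 53.5 ± 12.3 to 106 ± 10.5 FPKM, ATP5MC1 from 14.8 ± 0.964 to 27.9 ± 2.86 FPKM and NDUFB10 from 47.0 ± 3.73 to 68.3 ± 3.91 FPKM, and NDUFB3 had a log2 change of 0.74 ± 0.08 (SE). Camera gave an adjusted p of 1.22e-11, and adjusted p = 0.477 with an estimated correlation. The number that rose was 32 without shNC replicate 2, 4 without shWDR43 replicate 1 and 6 under median-ratio scaling. All genes with a symbol that starts with MT- made up 26.8% and 25.5% of the FPKM sum in shNC and 24.6% and 23.9% in shWDR43. Among them are the 13 mitochondrially encoded mRNAs, used as a sign of RNA quality. None of these 13 passed the test with limma, MT-ATP8 being nearest with a log2 difference of -0.32 (adjusted p = 0.178, unadjusted p = 0.0447), followed by MT-ATP6 at -0.24. As a list they were not called (camera adjusted p = 0.230), but were called downward without shNC replicate 1 (adjusted p = 0.0236), with 2 that fell, and 1 fell without shNC replicate 2. Glycolysis and hypoxia genes went both ways, with 1 of 32 rising and 3 falling, or 2 and 3 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.812). The glucose transporter gene SLC2A3 had a log2 change of -0.70, ALDOC of -0.44 and PFKFB4 of -0.43, and ANGPTL4 rose by 0.63. In this list 4 rose and 4 fell without shNC replicate 1, 6 rose and 4 fell without shNC replicate 2, and 1 rose and 1 fell without shWDR43 replicate 1 or 2.

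Genes of ribosome assembly, the process in which WDR43 is known to act, showed few changes with all 4 libraries and more without shNC replicate 1 or 2. The number of changed genes also rose over all tested genes when either library was left out. The added calls in these lists therefore do not by themselves set them apart. In the WDR43 partner and small-subunit processome list 0 members rose and 1 fell under upper-quartile scaling. With the deposited scaling 1 of 42 rose, RRP9 at a log2 change of 0.46. When adjusted over the list alone 0 did so (camera adjusted p = 0.424). Without shNC replicate 1, 5 rose and 4 fell, without shNC replicate 2, 7 rose and 1 fell, and without shWDR43 replicate 1 or under median-ratio scaling 0 rose. NOLC1, at 0.42, was the only member of the 20 in the RNA polymerase I list to rise, and 1 did so when adjusted over the list alone (camera adjusted p = 0.584). In that list 1 rose and 3 fell without shNC replicate 1, 5 rose without shNC replicate 2, and 0 rose without shWDR43 replicate 2 and under either scaling. In the large-subunit assembly list 2 of 40 rose, NOC2L at 0.40 and NIP7 at 0.50, and 2 when adjusted over the list alone (camera adjusted p = 0.818), but 5 rose and 2 fell without shNC replicate 1, 8 rose and 1 fell without shNC replicate 2, and 0 rose without shWDR43 replicate 1 or 2 and under either scaling. Cytosolic ribosomal protein genes differed between the shNC libraries. RPS15A had a log2 change of -0.45 and was the only one of 32 small-subunit genes to change, with 0 when adjusted over the list alone (camera adjusted p = 0.889). This list was called downward without shNC replicate 1 (adjusted p = 0.000593), where 8 fell, and upward without shNC replicate 2 (adjusted p = 0.000336), where 16 rose and 1 fell, and 0 changed without shWDR43 replicate 1 or 2 and under median-ratio scaling. Of 45 large-subunit genes 0 passed the test with limma, over all genes or the list alone, with RPL37 at a log2 difference of -0.36 (adjusted p = 0.0579, unadjusted p = 0.00435) and RPL14 at -0.56 (adjusted p = 0.0587, unadjusted p = 0.00460). This list was not called with all libraries (camera adjusted p = 0.320), was called downward without shNC replicate 1 (adjusted p = 1.58e-08), where 9 fell, and upward without shNC replicate 2 (adjusted p = 0.00639), where 13 rose and 2 fell, and 2 fell under upper-quartile scaling. None of 21 small nucleolar RNA host genes passed with limma, over all genes or the list alone, with SNHG12 at a log2 difference of 0.39 (adjusted p = 0.0629, unadjusted p = 0.00527) and SNHG10 at 0.52, and the list was called only without shNC replicate 2 (adjusted p = 0.0242, against 0.523 with all libraries), where 6 rose, while 3 fell without shNC replicate 1 and 1 rose without shWDR43 replicate 2. Several of these lists had a median that turned from positive to negative under upper-quartile scaling, the RNA polymerase I list at -0.01 and large-subunit assembly at -0.04 among them.

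**Figure D3:**
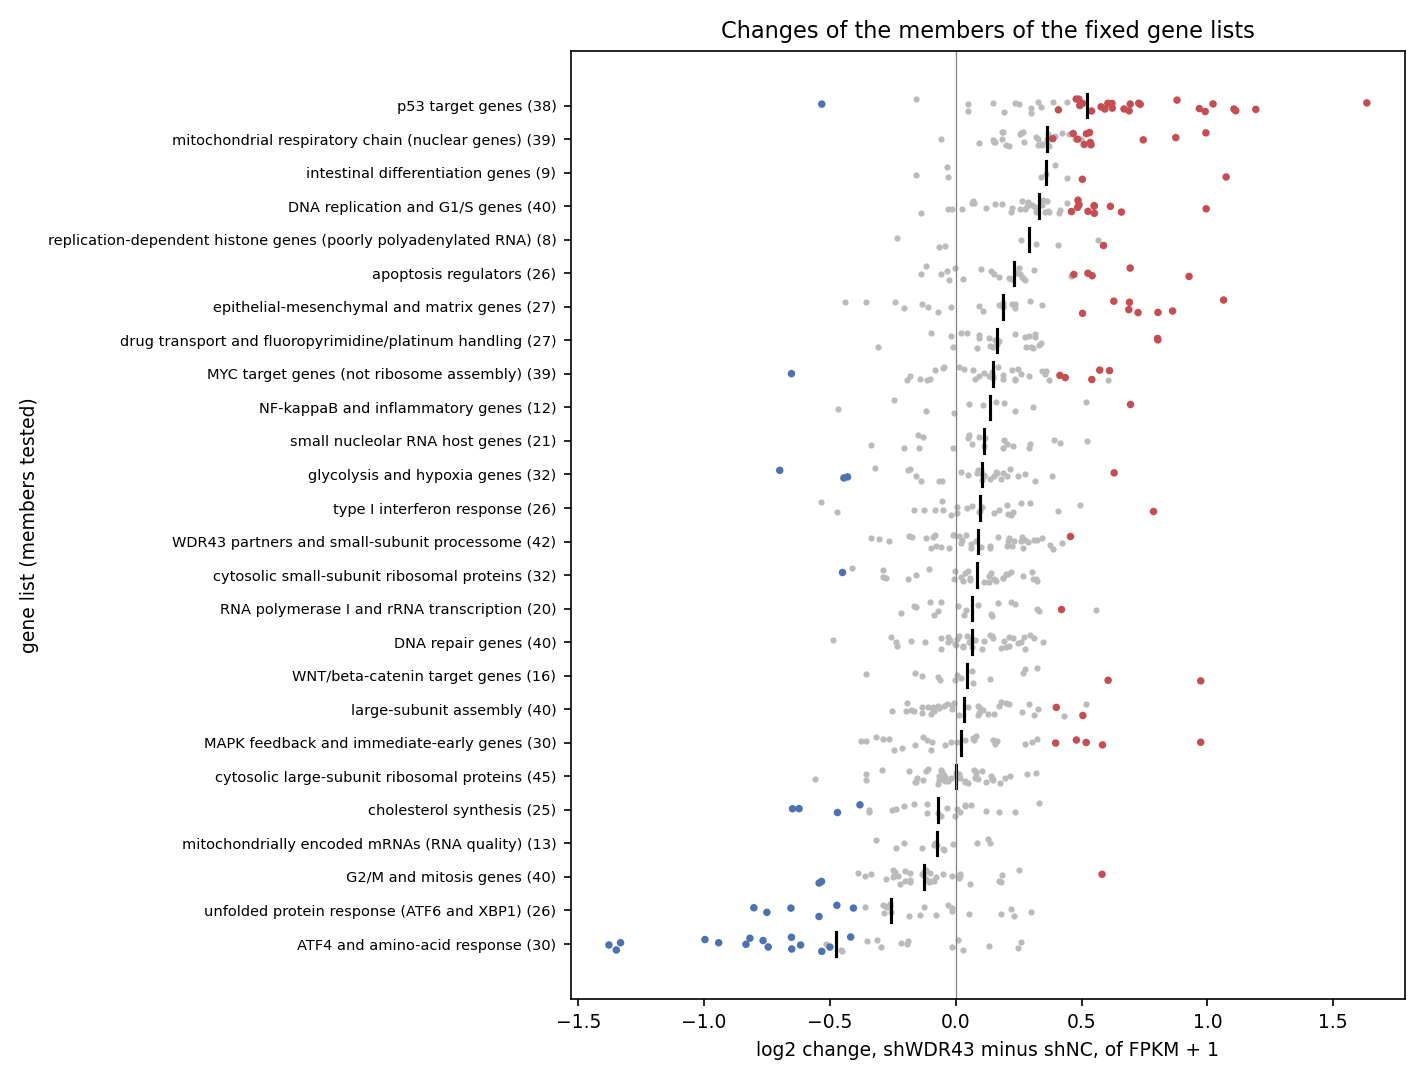
Log2 change (shWDR43 minus shNC, of FPKM + 1) of each tested member of the fixed gene lists with at least 5 tested members, with the list's median as a black bar. Red members rose and blue members fell at an adjusted p below 0.05 over all genes, and list medians run from -0.48 for the ATF4 list to 0.52 for p53 targets.

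MYC target genes outside ribosome assembly had 5 of 39 members that rose and 1 that fell, or 9 and 1 when adjusted over the list alone. CDC25A rose by 0.61, SHMT1 by 0.54 and EIF2S1 by 0.41 on the log2 scale, while the amino-acid transporter gene SLC7A5 had a log2 change of -0.65. SLC7A5 is also on the ATF4 list, so its fall is not separate from that result. The list was called upward (camera adjusted p = 0.0143) with adjusted p = 0.656 with an estimated correlation, and it was not called without shNC replicate 1 (adjusted p = 0.0732) or without shWDR43 replicate 1 (adjusted p = 0.142). In it 7 rose and 2 fell without shNC replicate 1, 18 rose and 1 fell without shNC replicate 2, 2 rose and 1 fell without shWDR43 replicate 1 and under median-ratio scaling, and 3 rose and 1 fell without shWDR43 replicate 2 and under upper-quartile scaling. Epithelial-mesenchymal and matrix genes had 8 of 27 members that rose and 0 that fell, or 9 and 1 when adjusted over the list alone. They included the epithelial laminin gene LAMB3 at 0.72 and the integrin gene ITGB4 at 0.69, both known components of epithelial adhesion to the basement membrane, and the urokinase gene PLAU at 0.63. Camera gave an adjusted p of 0.00676 for this list, and adjusted p = 0.322 with an estimated correlation. In the list of drug transport and fluoropyrimidine or platinum handling, 2 of 27 members rose, or 5 up and 1 down when adjusted over the list alone. The efflux pump gene ABCB1 went from 0.971 ± 0.0305 to 2.44 ± 0.0882 FPKM and the metallothionein gene MT1X had a log2 change of 0.80 ± 0.11 (SE). Camera gave an adjusted p of 0.00971, with adjusted p = 0.322 with an estimated correlation and 0.0946 without shWDR43 replicate 2. In this list 4 rose without shNC replicate 1, 8 rose and 1 fell without shNC replicate 2, and 1 rose without shWDR43 replicate 1 or 2.

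The remaining lists were not called by camera in the main design, and fry called 1 of them, WNT/beta-catenin targets (adjusted p = 0.0444). Intestinal differentiation genes had 2 of 9 members that rose, or 3 when adjusted over the list alone, CA2 at a log2 change of 1.07 and KRT8 at 0.50 (camera adjusted p = 0.0790), and the list was called without shNC replicate 2 (adjusted p = 0.00885), without shWDR43 replicate 1 (0.0440) and without shWDR43 replicate 2 (0.0143). The number that rose was 5 without shNC replicate 2, and 1 without shWDR43 replicate 1 or 2 and under either scaling. In the WNT/beta-catenin target list 2 of 16 rose, or 2 up and 1 down when adjusted over the list alone, CCND1 at 0.97 and DKK1, a WNT antagonist gene, at 0.61 (camera adjusted p = 0.533), while 3 rose and 1 fell without shNC replicate 2. CCND1, the cyclin D1 gene, is also on the MAPK feedback and immediate-early list, where 5 of 30 rose, or 6 up and 4 down when adjusted over the list alone, including TGFA at 0.58, DUSP5 at 0.52 and EPHA2 at 0.48. The median of that list was 0.02 while camera, which compares it with other genes, pointed downward (adjusted p = 0.889). In it 6 rose and 4 fell without shNC replicate 1, 7 rose and 3 fell without shNC replicate 2, 2 rose without shWDR43 replicate 1 or 2, 3 rose under median-ratio scaling, and 4 rose and 2 fell under upper-quartile scaling. BIRC3 was the member of 12 NF-kappaB and inflammatory genes that rose, with 2 up and 1 down when adjusted over the list alone (camera adjusted p = 0.524), while 2 rose and 1 fell without shNC replicate 1 or 2. ISG15 was the member of 26 type I interferon genes that rose, at 0.78, and 1 did so when adjusted over the list alone (camera adjusted p = 0.533), while 3 rose without shNC replicate 1 and 2 rose and 1 fell without shNC replicate 2. Of 8 tested replication-dependent histone genes, whose RNA is poorly polyadenylated, H2BC5 rose by 0.58, with 2 when adjusted over the list alone (camera adjusted p = 0.289, and 0.0336 without shNC replicate 2), and the number that rose was 3 without shNC replicate 2, 2 without shWDR43 replicate 2, and 0 without shNC replicate 1, without shWDR43 replicate 1 and under either scaling. Markers of other cell types were mostly below the filter. ACTA2 rose among 2 tested fibroblast markers, from 5.43 ± 1.47 to 10.8 ± 1.44 FPKM, CD68 among 2 tested leukocyte markers, and of the endothelial markers 0 reached the filter and the highest value was 0.164 FPKM. Levels of TP53INP1, NIP7, RPS15A, SHMT1, EIF2S1, ABCB1, HERPUD1, HSP90B1, STARD4, SREBF2, ANGPTL4, NDUFB3, CCND1, ITGB4, KRT8, SNHG12, SNHG10, ACTA2, CD68, MT-ATP8 and MT-ATP6 are uncertain too, because each overlaps another gene with a mean of at least 1 FPKM. The degree of uncertainty differs, as these overlaps ran from 1 bp, as for ANGPTL4, to 85776 bp for ABCB1.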

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

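The filter at 5 FPKM, upper-quartile scaling, the test against a 1.5-fold change, the crossed block, protein-coding genes alone and list tests without the filter or with a pseudocount of 0.1 were chosen after seeing the data. The count of 833 changed genes was 809 with a pseudocount of 0.1, 730 with robust settings off, 594 with upper-quartile scaling, 1031 at 5 FPKM and 1079 among protein-coding genes alone. It was 450 with median-ratio scaling, 17 without the filter and 3 against a 1.5-fold change. The cause of the drop without the filter was not tested. Leaving out a library gave 377 to 2586 genes, the low end without shWDR43 replicate 1 and the high end without shNC replicate 2. Genes changed at least 2-fold, counted on the log2 scale after the pseudocount, numbered 34. The number was 96 with a pseudocount of 0.1, 15 without the filter, 22 at 5 FPKM, where fewer genes are tested, and 3 against a 1.5-fold change. Changed list members numbered 114, and 5 without the filter, 1 against a 1.5-fold change, 198 with the crossed block and 67 to 284 with a library left out. Of 84 named genes and list examples, 70 passed the threshold, and 61 lost the call without the filter, 68 against a 1.5-fold change, 15 under median-ratio scaling, 8 under upper-quartile scaling, 21 without shWDR43 replicate 1, 19 without shWDR43 replicate 2, 12 under the replicate block and 2 without shNC replicate 1. Genes that gained a call numbered 8 without shNC replicate 2, 5 without shNC replicate 1 and with the crossed block, 4 at 5 FPKM, 3 among protein-coding genes alone and 2 under upper-quartile scaling. Of the named genes, 0 reversed past the threshold.

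Replicate numbers are shared between the groups, but nothing states that they mark a shared day or culture. The deviations of same-numbered libraries correlated at -0.147 across 13303 genes, which are not independent replicates. The replicate block gave 563 changed genes, 413 higher and 150 lower, and changed no list call. With the numbers crossed, the block gave 1954.

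Of 26 lists, camera called 11 and fry 6, and camera with an estimated correlation called 0. With an estimated correlation the adjusted p was 0.268 for p53 targets, 0.322 for G1/S, apoptosis, unfolded protein response, cholesterol, epithelial-mesenchymal and drug handling genes, 0.328 for ATF4 and G2/M genes, 0.477 for the respiratory chain and 0.656 for MYC targets. With fry it was 0.116 for MYC targets, 0.104 for G2/M, cholesterol and respiratory chain genes, 0.0575 for apoptosis and ATF4 genes, and 0.0444 for WNT targets, a call that camera did not make. At 5 FPKM the calls of MYC targets (0.0763), drug handling (0.0802) and apoptosis (0.0577) were lost, with fewer genes tested. Intestinal differentiation genes were called with upper-quartile scaling (0.0309), the crossed block (0.0380) and no filter (0.0437). With each library left out in turn, adjusted p ran from 0.0011 to 0.142 for MYC targets, 0.0115 to 0.0946 for drug handling, 0.00885 to 0.157 for intestinal genes, 0.0236 to 0.660 for mitochondrially encoded mRNAs, 0.0336 to 0.876 for histone genes and 0.0242 to 0.756 for small nucleolar RNA host genes. It ran from 0.000336 to 0.660 for small-subunit and from 1.58e-08 to 0.660 for large-subunit ribosomal protein genes. The direction of both lists reversed with the shNC library left out, to 0.000593 downward for the small subunit without shNC replicate 1 and to 0.00639 upward for the large subunit without shNC replicate 2. The calls of p53, ATF4, G1/S, G2/M, unfolded protein response, cholesterol, respiratory chain, apoptosis and epithelial-mesenchymal lists held with each library left out. Settings that need counts (edgeR with other factors, DESeq2, limma-voom and a CPM filter) were not run, because the values are not counts, and what depth limits is unknown for the same reason.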

Other observations

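The 5 lists described first, and all tests below except that of lower levels, were chosen after the results were seen. Genes of the vacuolar proton pump, which acidifies lysosomes, had 6 of 17 tested members that rose and 0 that fell, with a median log2 change of 0.31. ATP6V0D1 had a log2 change of 0.83 ± 0.11 (SE), and ATP6V1A went from 12.1 ± 1.43 to 20.1 ± 0.0926 FPKM (mean ± SD, n = 2 per group). Lysosomal enzyme and membrane protein genes had 7 of 30 members that rose and 0 that fell, among them LAMP1 and the cathepsin gene CTSL, and CD68 and CTSD, which overlap other expressed genes and are uncertain. Proteasome subunit genes had 7 of 31 members that rose and 0 that fell, with PSMB3 at a log2 change of 0.62 and PSMD2 at 0.42. Unadjusted camera p-values were 3.19e-06, 2.11e-06 and 2.35e-07 in this order, and 0.0380, 0.0788 and 0.271 with an estimated correlation. The list medians stayed positive under upper-quartile scaling, at 0.23, 0.19 and 0.22. Their medians in each pair of a shWDR43 and a shNC library ran from 0.27 to 0.42, 0.22 to 0.30 and 0.16 to 0.40, in this order. The numbers that rose moved with the library left out and with scaling, as did the count over all tested genes. They were, in this order, 7, 11 and 10 without shNC replicate 1, 11, 16 and 22 without shNC replicate 2, 5, 1 and 2 without shWDR43 replicate 1, 5, 1 and 4 without shWDR43 replicate 2, 3, 2 and 1 under median-ratio scaling and 4, 2 and 5 under upper-quartile scaling, and 1 proteasome gene fell without shWDR43 replicate 2.

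Aminoacyl-tRNA synthetase genes were looked at by compartment. Of 20 cytosolic genes 7 fell, AARS1, CARS1, SARS1, TARS1, MARS1, YARS1 and GARS1, and FARSB rose, with an unadjusted camera p of 0.000398 and a p of 0.185 with an estimated correlation. AARS1, CARS1 and GARS1 are also on the fixed ATF4 list, so their falls are not separate from that result. MARS1 overlaps DDIT3, YARS1 overlaps S100PBP and GARS1 overlaps GARS1-DT, each on the opposite strand, so these levels are uncertain. CARS1 went from 41.3 ± 0.608 to 24.2 ± 1.62 FPKM and GARS1 from 91.5 ± 22.8 to 51.1 ± 9.66 FPKM. Of 17 mitochondrial genes 0 changed, with limma, and their median log2 difference was 0.11, against -0.12 for the cytosolic genes. Without shNC replicate 1 or 2, 3 cytosolic genes rose and 7 or 8 fell, without shWDR43 replicate 1 or 2, 0 rose and 5 or 6 fell, and without shNC replicate 2, 1 mitochondrial gene rose. The difference between both lists was not tested.

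Of 40 G1/S genes 11 rose and 29 did not pass (adjusted p = 0.322 for the list with an estimated correlation), while CDKN1A, an inhibitor of entry into S phase, rose, and 17 rose without shNC replicate 1, 25 without shNC replicate 2, 5 without shWDR43 replicate 1 and 4 without shWDR43 replicate 2. A single shNC library out of line is argued against by the lowest of the 4 library-pair medians of the list, 0.28, and scaling by the median under upper-quartile scaling, 0.25. A larger share of cells in G1 or early S and a smaller share in G2 and mitosis stays open: the G1/S median exceeded the G2/M median by at least 0.41 in each of 4 library pairs, but this restates the list calls and does not test the explanation. Cell-cycle phase was not measured, and a direct effect on these genes stays open as well.

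Of 39 nuclear respiratory chain genes 11 rose and 28 did not pass (adjusted p = 0.477 for the list with an estimated correlation and 0.104 with fry), 32 rose without shNC replicate 2 and 4 without shWDR43 replicate 1, and the list has short transcripts, with a median length of 662.5 nt against 961.5 nt for tested genes. Random lists of like annotated length and level mostly changed less: the medians of 10000 had a 95th percentile of 0.15, against 0.36 for the list (percentile 100). These lengths are medians over all GENCODE transcripts of a gene, not over those expressed. The random lists also lack the estimated correlation of 0.43 between the list's genes. A gain of short transcripts is therefore not excluded. shNC replicate 1 being out of line is argued against by the lowest library-pair median of 0.26, although shNC replicate 2 was itself above shNC replicate 1 by a median of 0.18. A rise of all mitochondrial transcripts is argued against by the 13 mitochondrially encoded mRNAs, whose highest library-pair median was 0.01 (0.00839). An effect of the hairpin on these genes stays open, as do RNA quality and culture differences between the groups.

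Genes other than protein-coding ones made up 26.5% of the 196 that fell, 3.30% of the 637 that rose and 12.8% of those tested, and the share of those that fell and of those that rose was 14.1% (75 of 533) and 5.13% without shNC replicate 1, 20.4% (160 of 784) and 3.55% without shNC replicate 2, 38.6% (51 of 132) and 8.98% without shWDR43 replicate 1, and 44.5% (61 of 137) and 5.81% without shWDR43 replicate 2. They include any entries without a position in GENCODE release 29, whose type is unknown and may be protein-coding. Lower levels of these genes are argued against by 10000 level-matched draws, with a median share of 10.2% and a highest share of 18.9% (percentile 100). A candidate explanation for part of this is unspliced or genomic RNA in shNC replicate 1: sense-intronic, antisense and processed pseudogene entries, 5, 14 and 11 of the 52 that fell, had median log2 differences of at least 0.00112, -0.0381 and -0.0379 from shNC replicate 2, but of at most -0.18, -0.11 and -0.16 from shNC replicate 1, while protein-coding genes had 0.06 to 0.07 from both. In the same order, 0, 13 and 0 entries of these types rose, so antisense calls went both ways. LincRNAs and processed transcripts made up 9 and 6 of the 52, and 4 and 0 entries of these types rose. For them the explanation stays open. Their medians were at least -0.0529 and -0.0920 from shNC replicate 2 and at most -0.07 and -0.11 from shNC replicate 1. The number of these genes that fell did not drop without shNC replicate 1, so the share of 14.1% does not show that the falls came from that library, and a change with the hairpin stays open.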
